A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

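Chromatin of budding yeast (Saccharomyces cerevisiae) strain BY4741, a standard haploid laboratory strain, was mapped in 2 libraries, 1 from wild-type cells and 1 from cells that lacked FUN30. FUN30 encodes an ATP-dependent chromatin remodelling enzyme. Per the labels' protocols, cells grew in rich medium and were fixed with paraformaldehyde. Crude nuclei were then digested with micrococcal nuclease, which cuts the DNA between nucleosomes, and the DNA of single nucleosomes was purified from a gel and sequenced. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The genome build, the read counts, the nucleosome caller and its settings are not given in the sources used here.

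Each deposited file lists the nucleosome calls of 1 library, with a chromosome number, a centre in bp, a width in bp and an occupancy signal in a column headed occ, per the file headers. Nothing was pooled across libraries in these files. The deposited occupancy signal is not a read count, and the depth of either library is unknown. The authors' scaling of this signal is not given in the sources used here. At 1001 evenly spaced quantiles the occupancy signal of the deposited files differed between the libraries by at most 0.0177%. The distribution of this signal over calls was therefore nearly identical in the libraries, its total followed the number of calls, and only its distribution along the genome was compared. The lowest deposited occupancy was 0.0824 in both libraries, so weaker nucleosomes were absent from the lists.

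The build of the files was tested against the positions of 6002 open reading frames of assembly R64. The average coverage by calls around reading frame starts was compared between 4 parts of each chromosome with equal numbers of genes, for both strands. The displacement from R64 was -378.5 to -370.0 bp in parts 2 to 4 of chromosome 11, and -106.5 to -93.5 bp in the same parts of chromosome 10. On the other chromosomes its median was -15.0 bp, with a range of -37.5 to -2.5 bp over 52 parts. Parts whose profile correlated below 0.7 with the mean profile were left out, and 60 of 64 were kept. The files were therefore not on R64, and coordinates were not converted. No call was assigned to a gene through R64 positions, also on chromosomes where the displacement was small. R64 served only for the name, chromosome, length and neighbours of FUN30. The analyses planned before the data were examined that need gene positions were not run. These were the length of the nucleosome-free region at gene starts, the shift by rank from the gene start, the gene lists (amino acid and carbohydrate metabolism, stress response, meiosis, phosphate response, mating, ribosomal proteins, ribosome biogenesis, subtelomeric families, silent mating loci and chromatin regulators) and the check of the marker genes HIS3, LEU2, MET17 and URA3. The rule that fixed which genes to name was applied to gaps between nucleosomes in place of genes. It named the 12 gaps with the largest lengthening and the 12 with the largest shortening among gaps whose flanking calls were above the lower quartile of occupancy in both libraries. Other single positions named are extremes of their kind, chosen after their values were seen. The rule also marked places within 20 kb of a chromosome end as uncertain. That mark was given only to the call at 487 on chromosome 3, and other named positions may lie near an end too.

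All coordinates are those of the deposited files. Calls on chromosomes 1 to 16 were compared. A wild-type call and a fun30 deletion call were paired when each was the nearest call to the other and their centres lay at most 73 bp apart. A pair counted as shifted when its centres differed by 20 bp or more. Both numbers were fixed before the data were examined. A wide gap was a pair of neighbouring calls that were paired and neighbouring in both libraries, with a distance between centres of 220 to 450 bp in the mean of both libraries. Taking the mean kept the choice of gaps from favouring either direction. Wide gaps include nucleosome-free regions and places where a weak nucleosome was not called, and without gene positions they have no orientation. Distances between centres were preferred to distances between call edges because call widths correlated across pairs with r = 0.122 only. Rank 1 is the nucleosome that flanks the gap, and ranks rise away from it. Regular spacing was the share of neighbouring calls with centres from 140 to below 190 bp apart. These definitions were made after the build had been tested and spacing had been looked at.

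With 1 library per genotype there is no replicate check, and no test between genotypes was made. A difference between these libraries covers the genotype, the culture, the digestion and the library preparation together. Shares carry exact (Clopper-Pearson) 95% intervals, and differences of shares a 95% normal interval. Both cover counting error over calls only, and calls are not replicates of a genotype. Because shifts depended on occupancy, classes of nucleosomes were set against 10000 random sets with the same number of distinct nucleosomes, matched on 10 occupancy classes. Median occupancy ratios near chromosome ends were set against 2000 random sets without matching. Pairing, gap finding and run finding were tested on simulated data made from the 48019 wild-type calls. All 1000 calls moved by 40 bp were recovered (100%). So were all 413 gaps lengthened by 30 bp and a removed run of 18 calls. The calls moved by 40 bp were drawn from calls without close neighbours, and other calls were jittered little or not at all. These simulations check the code and do not measure the accuracy of pairing among crowded or noisy calls. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The alternatives were other pairing distances and shift thresholds, stricter occupancy thresholds, call edges in place of centres, another spacing window, neighbours of limited call width, and the omission of chromosome ends or of chromosome 1.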

Results

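The study compared nucleosome positions and occupancy between wild-type yeast and cells without Fun30, and its title places the question at nucleosomes near promoters. The wild-type library held 48019 nucleosome calls and the fun30 deletion library 48135, of which 48132 lay on chromosomes 1 to 16. The calls covered 5420 kb in the wild-type library and 5411 kb in the fun30 deletion library. The median call width was 113 bp in both libraries, and the SD of the widths was 22.8 bp in wild type and 21.1 bp in the mutant. The median occupancy was 0.210 in both, as the matched scale of the deposited values requires. There was 1 library per genotype, so the values below have no replicate error.

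The targeted gene was examined first. FUN30 (YAL019W) lies on chromosome I and has a length of 3396 bp in the gene table. On chromosome 1 of the files, 18 consecutive wild-type nucleosomes with centres from 115011 to 117922 had no partner in the fun30 deletion library, which had 0 calls between these positions. The next longest run of unpaired wild-type calls held 6 nucleosomes, on chromosome 8, and the longest run of unpaired calls in the fun30 deletion library held 7, on chromosome 3. Median occupancies in those runs were 0.0951 and 0.0960, close to the lowest deposited value, against 0.359 in the run on chromosome 1. Of the 18 nucleosomes, 3 had an occupancy above 1 (at 115011, 115334 and 115662, the highest being 2.60 at 115662), and the others ranged down to 0.0954. The call-free stretch of the mutant, 3888 bp from centre to centre, is longer than the reading frame of FUN30, and the run was the longest in either library. The position of FUN30 in the files was taken from this run, its chromosome and the length of the gene, since the gene table is on another build. The displacement from R64 was only -7.0 and -19.0 bp in parts 2 and 3 of chromosome 1, but the R64 position of FUN30 was not used as a check.

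The nucleosomes on both sides of this stretch were present in both libraries. On the side of lower coordinates, towards the neighbouring gene ATS1, the last nucleosome was at 114854 in wild type with an occupancy of 0.359, and at 114801 in the mutant with an occupancy of 0.314. It lay 53 bp further from the missing segment. The call was 110 bp wide in wild type and 85 bp wide in the mutant. Whether its place beside the missing segment affected the called centre was not tested. The nucleosome before it was at 114573 in wild type and at 114572 in the mutant. On the other side, towards LDS1, the first nucleosome was at 118688 in wild type and at 118689 in the mutant, with occupancies of 0.384 and 0.224.

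**Figure D1:**
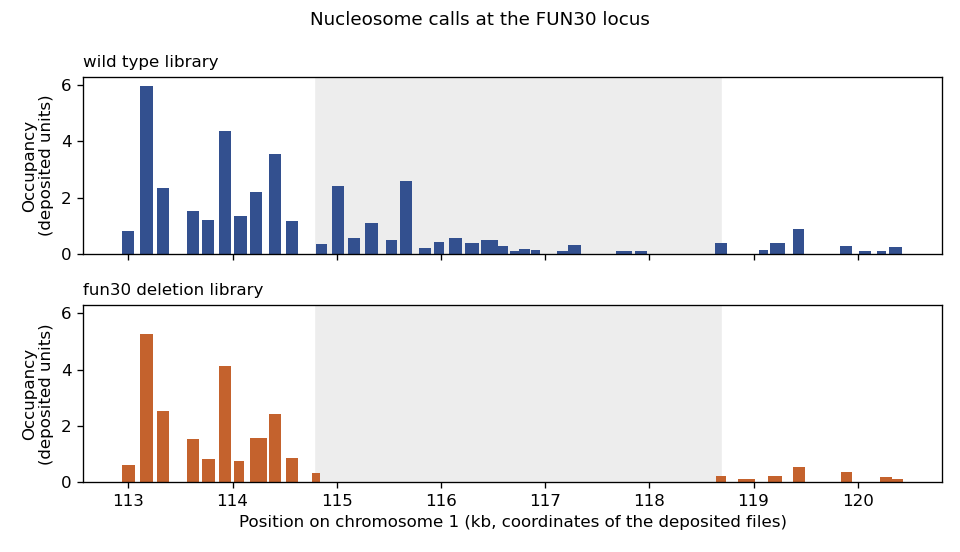
Nucleosome calls on chromosome 1 around FUN30 in the wild-type library (top) and the fun30 deletion library (bottom). Each bar is 1 call, as wide as the call in the file, and its height is the deposited occupancy; the grey band spans the centres of the mutant calls at 114801 and 118689, between which wild type had 18 calls with no partner and the mutant had 0.

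The next comparison asked how far nucleosomes lay from their wild-type place across the genome. Of the wild-type nucleosomes, 40794 (85.0%) had a partner in the fun30 deletion library. The median absolute displacement was 9 bp, with quartiles of 3 and 21 bp, and 37.9% of the pairs lay within 5 bp of each other. A displacement of 20 bp or more was seen in 10852 pairs, or 26.6% (95% interval 26.17 to 27.03%). The 2 directions along the chromosome were nearly equal, with 13.4% of pairs displaced to higher and 13.2% to lower coordinates. By chromosome the shifted share ran from 23.97% on chromosome 9 and 24.04% on chromosome 1 to 27.8% on chromosome 13.

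The displacement depended on occupancy. In the lowest of 10 occupancy classes 45.8% of the pairs were shifted (44.3 to 47.4%), and the median displacement was 18 bp. In the highest class 4.26% were shifted (3.67 to 4.93%), and the median displacement was 2 bp. The share fell at each step between these classes. Shifted nucleosomes were not more clustered than in shuffles at the scale of 20 neighbouring pairs. Among 2039 windows of 20 neighbouring pairs the variance of the number of shifted pairs was 4.55, and shuffling the shifts within occupancy classes 1000 times gave 4.26 to 4.74 in 95% of shuffles. The most shifted window held 13 of 20 pairs, which was also the median of the highest window in the shuffles.

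**Figure D2:**
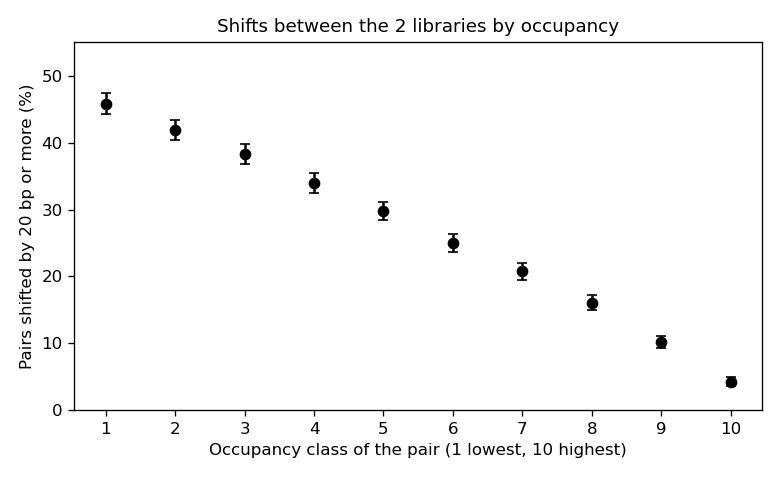
Share of nucleosome pairs displaced by 20 bp or more between the wild-type and fun30 deletion libraries (vertical axis, %) in 10 classes of equal size by occupancy (horizontal axis, 1 lowest, 10 highest). Points are the shares and bars exact 95% intervals for counting error; the share falls from 45.8% to 4.26%.

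Occupancy was compared within pairs. Log2 occupancy correlated between the libraries with r = 0.88 across nucleosomes, which are not independent replicates. The log2 ratio of the fun30 deletion to the wild-type library had a median of 0.01 and an SD of 0.50. A difference of 2-fold or more was seen in 1988 pairs (4.87%), with 1055 higher and 933 lower in the mutant library. The matched occupancy distributions favour a small median ratio and similar counts in both directions, so these values do not measure loss against gain. The lowest deposited occupancy of 0.0824 also limited how far weak calls could fall. Among nucleosomes above the lower quartile of occupancy in both libraries, the largest decrease was on chromosome 9 at 241098, where occupancy was 1.79 in wild type and 0.440 in the mutant at the same centre. It was followed by chromosome 13 at 91746, with 0.939 in wild type and 0.233 in the mutant. The largest increases were on chromosome 1 at 228730, from 0.166 to 0.657, and on chromosome 7 at 1047234, from 0.136 to 0.528. The mutant call of the chromosome 1 pair lay at 228693. These positions were not checked for nearness to a chromosome end, where the placement of reads is uncertain. The ratios of nucleosomes next to each other correlated with r = -0.01.

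Some calls had no partner in the other library. In wild type 7225 calls had no partner (15.05%, 14.73 to 15.37%), and in the fun30 deletion library 7338 (15.2%, 14.9 to 15.6%). Each call has at most 1 partner, so these counts follow from the number of pairs and the near-equal call totals and do not measure loss against gain. The unpaired calls had median occupancies of 0.117 in wild type and 0.115 in the mutant. Calls above the median occupancy with no call within a nucleosome's length of DNA in the other library numbered 89 in wild type, of which 12 belonged to the FUN30 run and 77 did not, and 75 in the mutant. In wild type the strongest of these were the FUN30 nucleosomes at 115662 and 115011, and the strongest one on another chromosome was at 779374 on chromosome 14, with an occupancy of 0.610. In the mutant the strongest were at 487 on chromosome 3, with 0.753, and at 414253 on chromosome 2, with 0.542. The call at 487 lies at a chromosome end and is uncertain, since the placement of reads in repeated sequences is not known.

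Gaps between nucleosomes were compared because the promoter-proximal nucleosomes of the study's question flank nucleosome-free regions. The median distance across 4878 wide gaps was 310.0 bp in both libraries, and the median change was 0 bp. The distance differed by 20 bp or more at 2073 gaps (42.5%, 41.1 to 43.9%). Gaps were longer in the mutant at 1027 of these (21.1%, 19.9 to 22.2%) and shorter at 1046 (21.4%, 20.3 to 22.6%). Neighbouring nucleosomes inside arrays, weighted to the occupancy of the gap-flanking ones, changed their distance by as much in 43.2% of cases. Gaps filled by a call in the other library were also similar in both directions. These gaps were taken in each library separately, unlike the 4878 wide gaps, whose flanks were neighbours in both libraries. Call totals and numbers of unpaired calls were nearly equal, which favours similar shares, so the shares do not measure loss against gain. A call lay inside 1876 of 7001 wild-type gaps in the mutant (26.8%, 25.8 to 27.9%), and inside 1762 of 6791 mutant gaps in wild type (25.9%, 24.91 to 27.01%). A call above the median occupancy did so at 2.11% of wild-type and 2.14% of mutant gaps.

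The gaps with the largest changes were found on many chromosomes. The 12 most lengthened gaps grew by 77 to 122 bp and lay on 8 chromosomes. The largest was on chromosome 13, with flanking centres at 726306 and 726619 in wild type and at 726241 and 726676 in the mutant, so that the distance went from 313 to 435 bp. On the same chromosome a gap at 75227 to 75425 went from 198 to 317 bp, and on chromosome 3 a gap at 72927 to 73135 went from 208 to 317 bp. In 9 of these 12 gaps both flanking nucleosomes moved outwards by 20 bp or more. The 12 most shortened gaps lost 70 bp or more and also lay on 8 chromosomes. The largest decrease was on chromosome 2, where a gap at 794211 to 794500 went from 289 to 186 bp. Its right flank moved by 73 bp, the largest distance at which calls were paired, so this pair may join different nucleosomes. On chromosome 11 a gap at 227114 to 227592 went from 478 to 382 bp, and on chromosome 9 a gap at 247607 to 248018 went from 411 to 317 bp. In 6 of these 12 gaps both flanks moved inwards by 20 bp or more. All 24 changes had the same sign when measured between call edges. Edge distances are computed from the same centres, so this is not a second measure. Pairing capped each displacement at 73 bp, so any change beyond 73 bp required both flanks to move. They are the extremes of 2325 gaps with flanks above the lower quartile of occupancy, and have no replicate check. Many flanks of the 24 named gaps were nonetheless below the median occupancy of 0.210, where shifts were more frequent. At the lengthened gap at 580870 on chromosome 13 the flanks had occupancies of 0.153 and 0.150 in wild type.

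**Figure D3:**
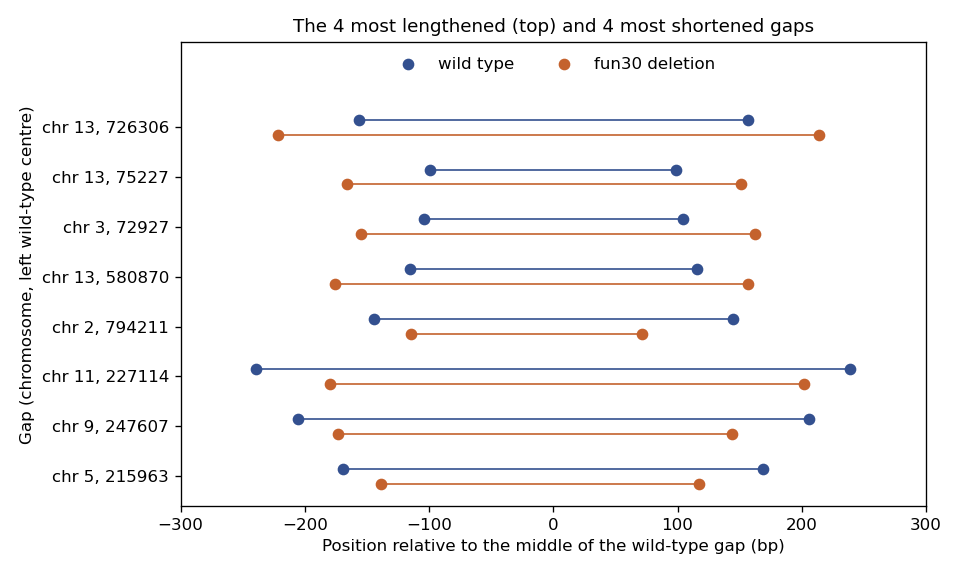
The 4 most lengthened (top) and 4 most shortened (bottom) wide gaps among those with flanking calls above the lower quartile of occupancy in both libraries. Dots are the centres of the flanking nucleosomes in the wild-type (blue) and fun30 deletion (orange) libraries, in bp from the middle of the wild-type gap; the top gap went from 313 to 435 bp and the fifth from 289 to 186 bp.

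Nucleosomes were then ranked by their place from a wide gap, because ranks from a gene start were not run. Wide gaps are not known to be promoters. Their median distance of 310.0 bp was close to the second peak in the distances between calls, at 324 bp. An uncalled weak nucleosome could also give such a distance. The median occupancy was 0.205 at rank 1 and 0.254 to 0.288 at ranks 2 to 5. The ranks therefore do not answer the question for promoter-proximal nucleosomes. Of 9756 flanking positions, held by 9114 distinct nucleosomes, 25.7% were shifted (24.9 to 26.6%). At each rank a nucleosome reached from 2 gaps counted once for each gap, also in the intervals. The share was 23.5% at rank 2, 22.6% at rank 3, 22.6% at rank 4 and 21.9% at rank 5 (19.6 to 24.4%). Random sets of nucleosomes with the same occupancies gave 28.5% at rank 1 (95% of sets from 27.6 to 29.1%), 24.6% at rank 2 and 23.9% at rank 3, so that rank 1 lay below its matched sets. Ranks 2 and 3 also lay below nearly all of their sets, with 1.44% and 2.27% of the sets lower. The share at rank 3 was at the lower edge of the range of 95% of its sets (22.61 to 25.31%). Ranks 4 and 5 lay within the range of 95% of theirs. With pairing up to 100 bp, 1.98% of the sets were lower at rank 2 and 1.95% at rank 3. For shifts of 40 bp or more these shares were 8.63% and 1.11%, and above the median occupancy 1.08% and 4.37%. Each nucleosome entered the random sets once, and the sets included nucleosomes with a close neighbour. Against nucleosomes with a neighbour at regular spacing (from 140 to below 190 bp) on both sides, weighted to the same occupancies, the difference of rank 1 was within counting error, and ranks 2 to 5 were not compared in this way. The regularly spaced nucleosomes, so weighted, were shifted in 26.7% of cases (25.2 to 28.2%). The flanking nucleosomes had no preferred direction, with 12.6% displaced away from the gap and 13.1% into it, and a median of 0 bp at each of ranks 1 to 5. A shifted nucleosome with a wide gap on both sides counted once in each direction.

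**Figure D4:**
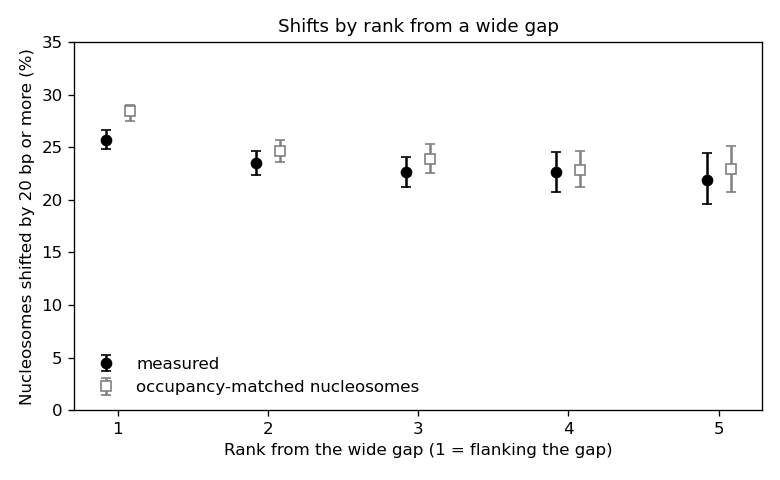
Share of nucleosomes displaced by 20 bp or more between the libraries (vertical axis, %) by rank from a wide gap (horizontal axis). Filled circles are measured shares with exact 95% intervals, and open squares the occupancy-matched shares with the range of 95% of random sets; at each rank the measured share lies below the matched one, by most at rank 1 (25.7% against 28.5%).

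The spacing of neighbouring nucleosomes differed between the libraries beyond counting error when calls of all widths were taken. Neighbouring calls were from 140 to below 190 bp apart in 29.3% of 48003 intervals in wild type (28.8 to 29.7%) and in 31.5% of 48116 intervals in the fun30 deletion library (31.0 to 31.9%). The difference was 2.20 percentage points (1.62 to 2.78). Among neighbours that were both between 100 bp and the wild-type upper quartile in width it was 0.936 points, with an interval that included 0 (-0.23 to 2.10). It had the same sign on each of the 16 chromosomes, with a counting interval that included 0 on most of them, from 1.23 points on chromosome 4 to 4.18 on chromosome 2. Intervals under 120 bp were less frequent in the mutant (18.9% against 19.6%), and so were intervals from 120 to below 140 bp (10.8% against 11.3%). Peaks in the distances between calls lay at 165, 324, 482 and 633 bp in wild type and at 167, 324, 488 and 639 bp in the mutant. The first peak was 1.56 times the mean level at distances beyond the third peak in wild type and 1.69 times in the mutant.

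**Figure D5:**
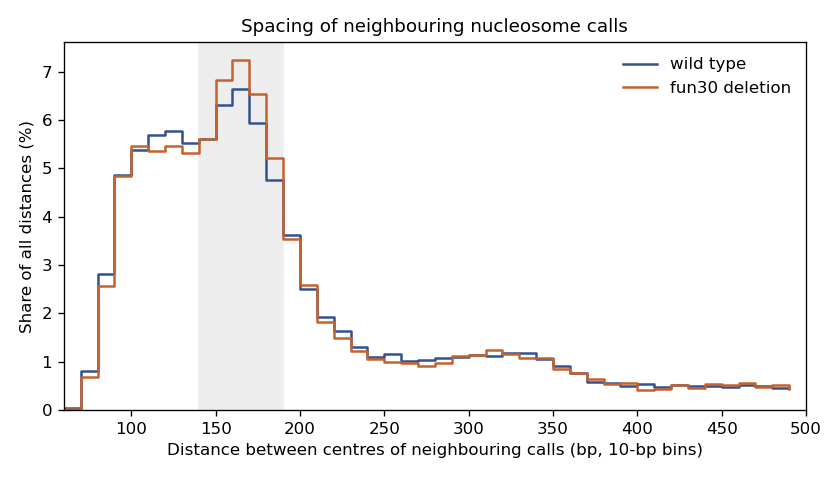
Distribution of distances between the centres of neighbouring nucleosome calls in 10-bp bins (horizontal axis, bp) as a share of all distances in the library (vertical axis, %), for wild type (blue) and the fun30 deletion (orange). The grey band marks distances from 140 to below 190 bp, which holds 29.3% of the wild-type and 31.5% of the mutant distances.

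Chromosome ends were compared because Fun30 is known to act in silent chromatin. Within 30 kb of a chromosome end 28.5% of 2354 pairs were shifted (26.7 to 30.4%), and occupancy-matched sets gave 27.7%. The median log2 occupancy ratio there was -0.02, just outside the range of 95% of random sets of that size (-0.01 to 0.03). Within 5 kb of an end it was -0.11 over 226 pairs, and random sets gave -0.07 to 0.08. The other 2128 of these pairs, 5 to 30 kb from an end, had a median of -0.01, inside the range of their random sets (-0.02 to 0.03). Near the ends of chromosome 3, the chromosome that carries the silent mating loci, 29.6% of 135 pairs were shifted (22.1 to 38.1%) against 27.7% in matched sets, and the median log2 ratio was -0.05 against a random range of -0.09 to 0.11. Chromosome ends hold repeated sequences, and how the authors placed reads that match several places is not given in the sources used here.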

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

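The fun30 deletion library held 3 calls on a chromosome numbered 17, outside the 16 nuclear chromosomes compared above, and the wild-type library held 0. They were at 16404, 59906 and 61932, with occupancies of 0.153, 0.118 and 0.0878. Groups of 1 library cannot be searched for outlying samples.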

How the results depend on the processing

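The settings for gaps, ranks, runs and spacing, and the omission of chromosome 1, were chosen after the data had been seen; the others were fixed beforehand. The shifted share of 26.6% became 23.6% with pairing up to 50 bp, 27.6% with pairing up to 100 bp, 15.6% among calls above the median occupancy, 49.4% for shifts of 10 bp or more and 8.31% for shifts of 40 bp or more. The share of changed wide gaps, 42.5%, became 47.7% between call edges, 16.99% for changes of 40 bp or more and 31.0% with flanking calls above the lower quartile of occupancy. The shifted share of gap-flanking nucleosomes, 25.7%, became 8.56% for shifts of 40 bp or more, 27.4% with pairing up to 100 bp and 10.9% above the median occupancy, where array nucleosomes weighted alike gave 12.1% (10.8 to 13.5%). For call edges the cause was not tested; the other moves follow from the thresholds or from the lower displacement of strong calls. The number of calls above the median occupancy could not test the ratio of call numbers, because the occupancy distributions are matched. The run at FUN30 held 18 or 19 calls under other pairing distances and 12 above the median occupancy. The difference in regular spacing was 1.63 to 2.21 percentage points under 5 other settings and fell to 0.936 (-0.23 to 2.10) among neighbours of limited call width, for which the cause was not tested. Other settings for gene starts, ranks from gene starts and gene lists were not run because the files and the gene table are on different builds. No paired analysis was possible because there is 1 library per genotype. Depth is unknown, so how much of the displacement of weak calls comes from few reads cannot be measured.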

Other observations

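Occupancy was spread unevenly over the genome in the same way in both libraries. The median occupancy was highest on chromosome 1 (0.260 in wild type, 0.253 in the mutant) and chromosome 3 (0.243 and 0.246), which are among the chromosomes with the fewest calls, and lowest on chromosome 16 (0.197 and 0.199). Of the 10 windows of 10 kb with the highest summed occupancy, 9 were shared by the libraries. They included 520 to 530 kb on chromosome 11 (47.4 in wild type and 47.8 in the mutant), 210 to 220 kb on chromosome 3 (46.0 and 47.0) and 50 to 60 kb on chromosome 9 (44.9 and 46.1), against a median window of 11.996 and 12.07. The window with the highest sum in wild type was the one at 110 to 120 kb on chromosome 1, which contains the FUN30 run, with 49.5 in wild type and 34.7 in the mutant. The 18 missing calls summed to 10.6, less than this difference, and some calls present in both libraries beside them were also lower in the mutant, such as the one at 114407 (3.55 in wild type and 2.41 in the mutant).

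Some tests here were chosen only after the result was seen: those of weak calls, of arrays moving as a unit and of helical steps. The first pattern is the more regular spacing in the fun30 deletion library. Weak wild-type calls near the occupancy floor are argued against only as its sole source. With calls below the median occupancy left out, the difference was 1.78 percentage points (1.00 to 2.55). Distances were then taken between the remaining calls and can skip a left-out call, so this is not the same measure. A change on a few chromosomes is argued against, since all 16 showed the same sign. Call width stays open, since among neighbours that were both between 100 bp and the wild-type upper quartile in width the difference was 0.936 points (-0.23 to 2.10). Noisier positions in the wild-type library stay open too: among neighbours 120 to 220 bp apart in the mean of both libraries, the ratio of the SDs of spacing (mutant over wild type) differed between the highest and the lowest of 4 occupancy classes by -0.0366 (-0.0698 to -0.0009), the outcome set beforehand as speaking against them, but the test was judged void after it was seen, because the SDs in the lowest class (31.2 and 31.0 bp) exceeded that of an even spread over this range (28.9 bp). In the upper 2 classes, with SDs below that limit, the ratio was 0.955 (0.933 to 0.980) and 0.956 (0.932 to 0.979). In the lower of these 2 classes both SDs were still close to the limit, which can hold a ratio near 1. A move towards 1 with occupancy could therefore be masked, and these ratios do not count for or against such noise. The genotype, as a hypothesis, cannot be told apart from differences in digestion or depth with 1 library each.

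The second pattern bears on whether neighbouring nucleosomes moved together, as arrays that slid as a unit would. The signed displacements of neighbours from 140 to below 190 bp apart correlated with r = 0.0527 across 11851 neighbours, where 1000 shuffles gave -0.02 to 0.02 in 95% of cases. That is above the shuffled range but far below the 0.3 set, after the result was seen, for arrays moving as a unit. It argues against such movement as the general pattern for neighbours at this spacing. Movement of a minority of arrays, or movement masked by the scatter of weak calls, is not excluded. At 1 nucleosome further r was 0.02 (shuffles -0.03 to 0.03). Closer neighbours correlated more strongly, with r = 0.40 under 120 bp and r = 0.24 from 120 to below 140 bp. Shuffles gave -0.03 to 0.03 for both. No neighbouring calls lay closer than 60 bp in either library. This limits how far the displacements of close neighbours can differ and favours a positive r, and the shuffles do not keep the limit. The shuffled range is therefore no chance level for these classes, and the values do not show joint movement. No explanation was tested for them.

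The third pattern is an excess of displacements of 10 to 12 bp among the best-occupied nucleosomes. In the highest of 10 occupancy classes 290 pairs were displaced by 10 to 12 bp and 227 by 6 to 8 bp, a ratio of 1.28, while in the other 9 classes the ratio ran from 0.81 to 1.00. A fixed grid of positions in the nucleosome caller is argued against, since the most frequent remainder of the centres modulo 10, 11 or 12 was only 1.04 times the even share. Steps of 1 turn of the DNA helix remain a candidate explanation and cannot be told from others here. A second excess at 20 to 22 bp would fit them, and the ratio there was 0.916 with a counting interval of 0.678 to 1.21.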
